A study of Mus musculus with 8 samples.

How the data were processed

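The samples were C57BL/6 mouse cells in 4 groups of 2 libraries at 5.5 mM glucose, 8 libraries in all. Per the labels' protocols, embryonic stem cells were kept with LIF or differentiated without it on gelatin, and Sca1-positive cells were sorted with magnetic beads. shRNA constructs were delivered by lentivirus with puromycin selection, and poly(A) RNA was sequenced on a Genome Analyzer IIx. The submitters' processing notes name BWA 0.5.9, SAMtools 0.1.17 and edgeR 0.19 without giving the role of each. The deposited values are whole-number read counts per RefSeq transcript, and judged from the values the authors had applied no scaling to them. The genome build, the counting program, the annotation release and the strand of the libraries are not given in the sources used here.

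The count table held 29614 transcripts (26257 coding and 3357 non-coding) and no column of another study. Transcript totals were 5920197 and 6788049 (mESC), 4321840 and 3354828 (untreated Sca1), 5692835 and 6004569 (NTC), and 3848243 and 6093498 (knock-down). Names and chromosomes came from a RefSeq gene table for 28985 transcripts and from GENCODE vM21 metadata for 173, and 456 kept their accession. For each of 23483 genes the transcript with the highest total was used, because 1920 of the 3684 genes with several counted transcripts had identical values in all of them, so a sum would count reads repeatedly. Genes that share reads, such as Filip1l with Cmss1 and the Pcdhg cluster, cannot be told apart.

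Counts were filtered with filterByExpr, scaled by TMM and tested in R 4.3.3 with edgeR 4.0.16. A negative binomial model of all 8 libraries with 1 mean per group (residual degrees of freedom 4, common dispersion 0.0133) was tested by robust quasi-likelihood F tests with Benjamini-Hochberg adjustment, and genes were called at an adjusted p of 0.05. Rises and falls in the text are calls unless a value is said not to pass. Standard errors were the fold change over the square root of F. The 3 comparisons were untreated Sca1 against mESC, knock-down against NTC, and NTC against untreated Sca1. Levels are TMM-scaled CPM, log-CPM used a prior count of 2, and chromosome medians used genes of at least 10 CPM. For a gene with 0 counts in a group, the least fold was computed with 3 counts there. With 1 to 3 counts, a ratio of counts with an exact 95% counting interval was used.

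Lists were tested with camera (limma 3.58.1, preset correlation 0.01) when at least 5 genes were tested, and again with a correlation estimated per list. Calls were also lost in lists whose estimate was below the preset, so a loss with the estimate does not by itself show correlation among members. The 34 lists, with 687 genes, were written from general knowledge before the data were examined. They covered core and naive pluripotency, primed epiblast, smooth muscle contractile genes, the SRF and MRTF axis, fibrillar matrix and basement membrane, mesenchymal transition, epithelial junctions and keratins, primitive streak and early mesoderm, extraembryonic and definitive endoderm, trophectoderm, neuroectoderm, endothelium, blood cells, cardiac and skeletal muscle, and Ly6 and vascular progenitor surface genes. Further lists covered interferon response, p53, TGF-beta, YAP and TEAD, NF-kB, Wnt and Notch targets, S phase, G2 and mitosis, glycolysis, the ATF4 and unfolded protein response, cholesterol synthesis, histone lysine methylation enzymes, Hox, imprinted, germline and 2-cell genes, replication-dependent histones, mitochondrially encoded genes and sex-linked genes.

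Genes were named by a fixed rule. It took Setd7, Ly6a, Pou5f1, Nanog, Sox2, Acta2, Tagln and Cnn1, and in each direction the 10 largest called changes of genes with a full symbol, a mean of at least 20 CPM in the higher group and no overlap between the libraries compared. In each list that was called or had at least 5 called members, it took up to 4 members with the smallest p. Genes named outside it, among them all that are listed for counts of 5 or fewer, the genes of chromosomes 15 and Y and those that follow NR_046233, were chosen after their values were seen. The code was tested on simulated data with known changes. It recovered 14.9%, 28.4% and 26.9% of 1.5-fold changes, 64.2%, 67.2% and 73.1% of 2-fold changes, and 90.9%, 92.4% and 90.9% of 4-fold changes in the 3 comparisons, and called 5, 4 and 10 unchanged genes. Of 20 shifted and 20 unshifted simulated lists it called 20 and 0. Genes were drawn independently there, so this does not cover lists of correlated genes, such as the primed epiblast list (estimated correlation 0.58).

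Alternatives planned beforehand were RLE factors, library totals only, DESeq2 1.42.0, no filter, a filter at 5 CPM, a fit of the compared groups only, the number in the sample descriptions as a block, a threshold of 1.5-fold, each library left out, and untreated Sca1 cells as control of the knock-down. Camera with an estimated correlation, fry, and a prior count of 0.5 for library similarity were planned too. Alternatives added after the data were seen were summed transcripts, removal of NR_046233 with the genes that follow it, removal of the 2 code 56 libraries, removal of genes on chromosomes 15 and Y, and, for genes below both groups, removal of chromosome 6, Pcdhg genes, unnamed records and repeats of identical counts. Simulated mixtures of NTC and mESC profiles were also added then.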

Results

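Poly(A)-selected RNA of 8 mouse cell samples was sequenced in 4 groups of 2. The groups were undifferentiated embryonic stem cells (mESC), untreated Sca1 cells sorted after differentiation of such cells, Sca1 cells with a non-target shRNA construct (NTC), and Sca1 cells with an shRNA against Set7 (knock-down). Set7, encoded by Setd7, is a lysine methyltransferase that acts on histone H3 and on other proteins. Sca1, encoded by Ly6a, is a surface protein used to isolate progenitor cells, and the series asks what Set7 does on the way from stem cells to smooth muscle. Counts summed over genes were 4288553 and 5080266 in the mESC libraries and 3097411 and 2507938 in the untreated Sca1 libraries. They were 4079756 and 4301485 in the NTC libraries and 2790736 and 4406728 in the knock-down libraries. Below, levels are counts scaled to library size (CPM), given as mean ± SD of n = 2 libraries, and log2 fold changes carry their standard error (SE). The labels do not say that the replicates are separate cultures, so p-values measure the spread between these samples. That spread was estimated jointly over all 8 libraries. Replicates of mESC and of untreated Sca1 cells differed far more than those of NTC and knock-down cells. P-values for the knock-down against NTC therefore rest in part on libraries outside that comparison.

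Setd7 (NM_080793, chromosome 3) stood at 11.2 and 16.5 CPM in the mESC libraries and at 76.1 and 66.1 CPM in the untreated Sca1 libraries. It stood at 60.6 and 66.5 CPM with the NTC construct and at 14.0 and 10.7 CPM in the knock-down. Every knock-down library thus lay below every NTC library. The stated 21-base shRNA target, CCGTGTTCAGAGATACCAAAT, matched 1 annotated transcript exactly, Setd7-201. The match lay in exon 8 of 8, in the 3' UTR, on the minus strand of chromosome 3 at 51520958 to 51520978 (GRCm38, GENCODE vM21).

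**Figure D1:**
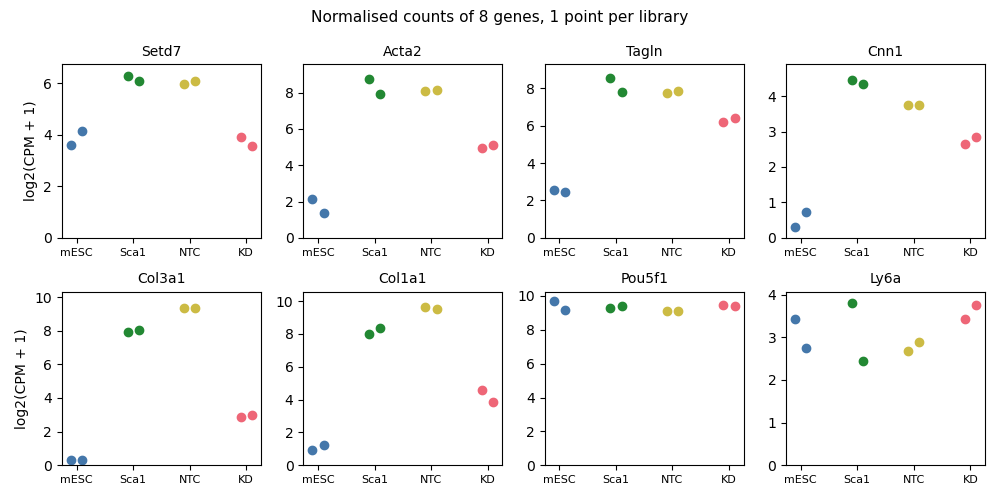
Normalised counts of 8 genes on the scale log2(CPM + 1), with 1 point per library and 2 libraries per group (mESC; Sca1, untreated Sca1 cells; NTC, non-target construct; KD, knock-down). Setd7 and Acta2 were low in mESC and knock-down libraries, Col3a1 ranged from 0.224 CPM in mESC to 656 CPM with the NTC construct, and Pou5f1 stayed between 544 and 708 CPM in the group means.

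The comparison of untreated Sca1 cells with mESC asks what the differentiation step changed. Contractile genes of smooth muscle rose. Acta2 (NM_007392), smooth muscle alpha-actin, rose from 2.48 ± 1.34 to 334 ± 129 CPM (log2 7.07 ± 0.35 SE, n = 2 per group; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 6.49e-08). Tagln (NM_011526), a calponin-related actin-binding protein, rose by 6.03 ± 0.25, and Cnn1 (NM_009922), calponin 1, rose by 5.40 ± 0.42 on the log2 scale. Setd7 itself rose by 2.36 ± 0.20 (adjusted p = 6.24e-08 by the same edgeR test), and by 2.71 and 1.97 within library codes 34 and 56 of the labels. The level of Ly6a did not differ detectably, at 8.68 ± 6.04 CPM in untreated Sca1 cells and 7.77 ± 2.91 CPM in mESC (edgeR adjusted p = 0.671).

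Of 13966 genes tested, 2612 were higher and 2351 lower in untreated Sca1 cells than in mESC, 1536 and 913 of them by more than 2-fold. The largest rises included the fibrillar collagen gene Col3a1, with 1369 counts against 2 (ratio 1109, 95% counting interval 307 to 9169), and the adhesion-modulating matrix gene Tnc, with 717 counts against 1 (ratio 1162, interval 208 to 45958). Cardiac actin Actc1, the network collagen Col8a1 and the macrophage growth factor Csf1 had no count in mESC and were at least 191-fold, 80.2-fold and 68.1-fold higher. Col1a1 rose by 7.99 ± 0.28, and Pcdh18, Acta1 and Pmp22 were the other largest rises, each from 1 to 3 counts in mESC. The counting intervals and the at-least folds cover counting error only. The largest falls were those of the citrate transporter gene Slc13a5 (-4.52 ± 0.29, from 58.6 ± 5.96 to 2.36 ± 1.46 CPM), the oocyte and embryo gene Khdc3 (-3.79 ± 0.24), Adgrg6, Myo7a, Fgf10, Trf, Efhc2, the germ-cell RNA-binding gene Dazl (-3.07 ± 0.21), Mitf and Hydin.

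The pluripotency factors Pou5f1, Nanog and Sox2 moved little. Pou5f1 (Oct4) stood at 648 ± 34.7 against 708 ± 189 CPM (log2 -0.13 ± 0.15, edgeR adjusted p = 0.540), and Nanog at 186 ± 28.9 against 194 ± 1.85 CPM (-0.06 ± 0.12, adjusted p = 0.764). Sox2 fell by 0.39 ± 0.13 (edgeR adjusted p = 0.0239). That call was lost without mESC replicate 1 (0.159), untreated replicate 1 (0.0675) or 2 (0.102), or knock-down replicate 1 (0.0508), and the alternatives tried ranged from 4.77e-05 to 1. Across the pluripotency list, 22 of 34 tested genes fell, among them the Nodal co-receptor gene Tdgf1 (-1.86 ± 0.15), the DNA demethylase gene Tet1 (-1.50 ± 0.13) and Klf5, and 23 fell when adjusted over the list alone (camera adjusted p = 0.000322, and 0.217 with an estimated correlation). Dppa3, Lin28a, Lefty1, Mycn and Zscan4c of that list rose. Of the genes of the primed epiblast, 10 of 11 rose, including Zic2, Dnmt3a and Lef1 (camera adjusted p = 1.31e-05, and 0.257 with an estimated correlation).

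Among 32 lists tested, camera called 17, with 14 toward higher and 3 toward lower expression. Hox genes, which set position along the body axis, went furthest. Of 31 tested, 30 rose and only Hoxc13 fell, the median being 4.81 (4.80 with genes at 0 counts set to their bound). In the smooth muscle list 19 of 24 rose and none fell, for example Tpm1 (3.16 ± 0.13), Cnn2 and Cald1. In the imprinted list 18 of 24 rose and none fell, led by the placental gene Peg10 (3.73 ± 0.14, to 2460 ± 35.4 CPM), Peg3 and Dlk1. Of the matrix list 22 rose and 10 fell among 33, and of the Wnt target list 11 of 16 rose and none fell. These 5 lists kept their calls with an estimated correlation (adjusted p = 0.0241 for Hox genes, 0.0485 for Wnt targets and 0.0484 for the rest). The counts adjusted over the list alone were the same for these 5.

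The 12 other calls, those of the pluripotency and primed epiblast lists included, were lost with an estimated correlation. The estimates for the endothelial (0.0069) and trophectoderm (-0.011) lists were below the preset 0.01. Correlation among members therefore does not account for the loss of those calls. Epithelial genes rose in 17 of 22 cases, such as the keratins Krt18 (4.21 ± 0.17) and Krt19, while Cdh1, Spint1 and Spint2 fell (adjusted p = 0.253 with an estimated correlation). Mesenchymal genes rose in 13 of 16 cases, such as Cdh2 and Twist1, and Ncam1 fell (0.159). Among YAP and TEAD targets 15 of 20 rose and Nt5e fell, among SRF and MRTF genes 11 of 16 rose and none fell (13 rose when adjusted over the list alone), and among TGF-beta targets 9 of 20 rose and Pmepa1 and Klf10 fell (each 0.0889). Among genes of the primitive streak 9 of 14 rose, Fgf8 and Wnt3 among them, and Pdgfra and Bmp4 fell (0.0889). Trophectoderm genes rose in 9 of 14 cases, such as Cdx2 (3.48 ± 0.18), and Tead4 fell (0.0889). Notch targets rose in 8 of 11 cases and Notch1 fell (0.217). Endoderm genes fell in 11 of 21 cases, led by Cubn (-2.31 ± 0.14) and Amn, while Thbd, Cxcr4, Plat and Snai1 rose (0.298). Endothelial genes fell in 7 of 14 cases, such as Pecam1 (-1.87 ± 0.13), and Flt1 rose (0.0889). Single leave-outs ended some of these calls. Without untreated replicate 1 the adjusted p was 0.433 for Cdh1, 0.115 for Spint1, 0.207 for Spint2, 0.0639 for Ncam1, 0.149 for Notch1, 0.160 for Zscan4c, 0.0905 for Cxcr4 and 0.447 for Snai1. Without untreated replicate 2 it was 0.175 for Klf10. The calls of Cdh1, Spint2, Ncam1 and Snai1 were also lost in other leave-outs, at adjusted p up to 0.366 (Ncam1 without mESC replicate 2).

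Lists of neuroectoderm, cardiac and skeletal muscle, Ly6 and progenitor surface genes, interferon response, p53 targets, NF-kB targets, S phase, G2 and mitosis, glycolysis, the ATF4 and unfolded protein response, cholesterol synthesis, histone lysine methylation enzymes, germline genes, replication-dependent histones and sex-linked genes were not called in this comparison (camera adjusted p of 0.0794 to 0.922). For 3 of them the median, the mean and the direction of the camera test differed in sign. The Ly6 list had a median of 0.11 and a mean of 0.38 with a downward test. The interferon list had a median of -0.34 and a mean of 0.69 with a downward test, and the histone list had a median of 0.12 and a mean of -0.07 with an upward test. The blood list had 4 tested genes and no test, and the mitochondrial list had no gene in the table.

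The knock-down was compared with the NTC construct to ask which genes depend on Set7 in Sca1 cells. Setd7 fell by 2.39 ± 0.20 on the log2 scale (63.5 ± 4.16 to 12.4 ± 2.28 CPM, n = 2 per group; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 1.71e-07), and by 2.08 and 2.57 within library codes 12 and 34. Several matrix genes fell further than Setd7. Col3a1 (NM_009930) fell by 6.60 ± 0.16, from 656 ± 2.10 to 6.65 ± 0.51 CPM (edgeR adjusted p = 1.05e-14). Postn, encoding periostin, had 237 counts with the NTC construct and none in the knock-down, at least 67.1-fold lower. Acta2 fell by 3.12 ± 0.25, from 276 ± 7.34 to 31.6 ± 3.13 CPM, and Tagln fell by 1.48 ± 0.18.

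In all, 593 genes were higher and 1404 lower in the knock-down, 113 and 796 of them by more than 2-fold. The other largest falls were those of the Notch-ligand-like imprinted gene Dlk1 (-5.75 ± 0.19, 424 ± 6.22 to 7.86 ± 0.26 CPM), Tnc (-5.65 ± 0.21), Col1a1 (-5.43 ± 0.20), Ccdc80, the TGF-beta-induced matrix gene Tgfbi (-4.76 ± 0.24), Col6a1, Dchs1 and the mesenchymal cadherin Cdh11 (-4.27 ± 0.31). The largest rises were smaller. Slc13a5 rose by 2.20 ± 0.26, Psors1c2 by 2.19 ± 0.26 and the POU factor gene Pou2f3 by 2.13 ± 0.24, followed by Krt23, the glutathione-degrading enzyme gene Chac1 (2.05 ± 0.32), Usp26, Prss50, Myb, Nupr1 and Tst, the last on chromosome 15. Pou5f1 (0.32 ± 0.15, edgeR adjusted p = 0.175), Nanog (0.33 ± 0.12, adjusted p = 0.0782) and Ly6a (0.92 ± 0.38, adjusted p = 0.126; on chromosome 15) did not pass. Sox2 rose by 0.48 ± 0.13 and Cnn1 fell by 1.11 ± 0.29. The calls of Sox2, Cnn1 and Nupr1 were each lost on leaving out any NTC or knock-down library, with adjusted p up to 0.263, 0.122 and 0.176.

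Of 19 lists called, 16 went down. In the matrix list 30 of 33 genes fell and none rose (31 when adjusted over the list alone; adjusted p = 0.00686 with an estimated correlation), with Col1a2 (-3.53 ± 0.13) beside the collagens named above. Among Hox genes 26 of 31 fell and none rose (28 over the list alone; 0.0132), such as Hoxd3 (-2.38 ± 0.18), Hoxd4 and Hoxb3. Among imprinted genes 16 of 24 fell and none rose (18 over the list alone; 0.0452), including Mest (-1.71 ± 0.12) and Peg3. No other call was kept with an estimated correlation, although the estimates for the Ly6 (-0.066) and neural (-0.0044) lists were below the preset 0.01. Smooth muscle genes fell in 16 of 24 cases and none rose (17 fell and 1 rose over the list alone; 0.0686), for example Tpm1 (-1.26 ± 0.12), Cald1 and Myl9. Mesenchymal genes fell in 14 of 16 cases (15 over the list alone; 0.0833), for example the intermediate filament gene Vim (-1.89 ± 0.15), Cdh2 and Cd44. TGF-beta targets fell in 12 of 20 cases, such as Tgfb2 and Ltbp1, while Klf10, on chromosome 15, rose (15 fell over the list alone; 0.0686). YAP and TEAD targets fell in 11 of 20 cases, such as Ccn1 and F3, and Nt5e rose (14 fell over the list alone; 0.121).

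**Figure D2:**
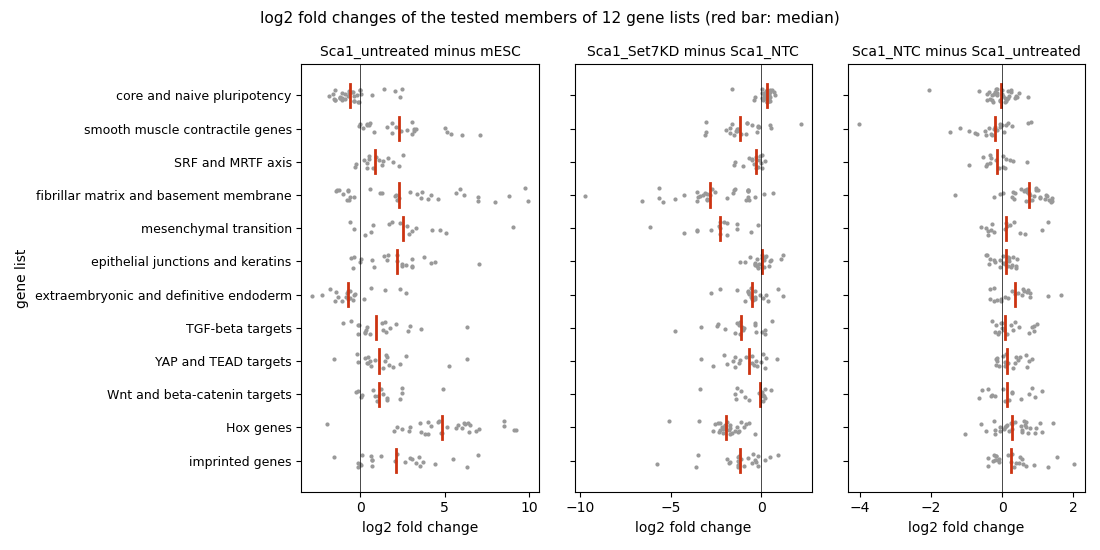
Fitted log2 fold changes of the tested genes in 12 lists, 1 panel per comparison, with a red bar at the median. Matrix, Hox, mesenchymal, imprinted and smooth muscle medians were above 0 in untreated Sca1 cells against mESC and below 0 in the knock-down against NTC, with Hox medians of 4.81 and -1.94.

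Smaller groups also moved. In the pluripotency list 8 of 34 genes rose, such as Utf1 (0.76 ± 0.14) and L1td1 (0.71 ± 0.13), and Zscan4c fell (11 rose over the list alone; adjusted p = 0.204 with an estimated correlation). Endoderm genes fell in 8 of 21 cases, such as Plat and Thbd, while Amn and Srgn rose (0.398). The neural genes Nes (-2.20 ± 0.15), Ncam1, Sox11 and Gap43 fell and Tubb3 rose among 12 (0.121). Ly6 and progenitor surface genes fell in 7 of 14 cases, such as Flt1 (-2.91 ± 0.19), Mcam and Itgb1, and Nt5e rose (0.133). The primitive streak genes Pdgfra, Hand1, Msgn1, Bmp4 and Foxc1 fell and Eomes rose among 14 (0.219). Of the Wnt targets 6 of 16 fell, such as Nkd1, Ccn4 and Notum, and Cdx1 rose (median -0.08, mean -0.57; 0.185). The Notch list lost Notch1, Notch3, Dll1 and Hes7 among 11 (0.219), the NF-kB list Csf1, Vcam1 and Nfkb1 among 14 with Sod2 higher (0.204), and the SRF list Ccn1, Zyx and Vcl among 16 (0.204). The DNA replication genes Mcm4, Cdc6 and Dscc1, the last on chromosome 15, rose among 25 of S phase (0.465), and no gene of the G2 and mitosis list passed although its median was 0.14 (0.461). Lists of primed epiblast, epithelial, trophectoderm, endothelial, cardiac, interferon, p53, glycolysis, ATF4, cholesterol, histone methylation, germline and replication-dependent histone genes were not called (camera adjusted p of 0.151 to 0.830). The cholesterol list (median -0.04), the histone methylation list (median 0.05, mean -0.07) and the germline list (median -0.20) each had an upward test direction.

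Leaving out knock-down replicate 2 ended the calls of Zscan4c, Vcl, Zyx, Eomes, Hand1, Msgn1, Bmp4, Srgn, Tubb3, Sox11, Gap43, Nt5e, Klf10, Sod2, Nfkb1, Vcam1, Cdx1, Notch1, Notch3, Dll1, Hes7, Mcm4, Cdc6 and Dscc1, with edgeR adjusted p between 0.0523 and 0.529, and those of the SRF (camera, 0.107) and primitive streak (0.0836) lists. All of these genes but Zyx, Sox11, Gap43, Vcam1 and Notch3 were also lost in other leave-outs, at adjusted p up to 0.351 (Zscan4c without NTC replicate 1). The SRF list was lost without NTC replicate 1 as well (0.0510). Against untreated Sca1 cells instead of NTC cells, Notch1 was higher in the knock-down by 0.56 (edgeR adjusted p = 0.0138), and Pdgfra, Cdx1 and Eomes changed sign without passing. Against that control Nupr1, L1td1, Vcl, Bmp4, Hand1, Msgn1, Nfkb1, Notum, Notch3, Dll1, Hes7, Cdc6, Mcm4, Klf10, Srgn and Zfy1 kept their direction but did not pass (edgeR adjusted p of 0.0501 to 0.975). The endoderm (camera adjusted p = 0.795), Ly6 (0.549), NF-kB (0.0606), Wnt (0.0841), Notch (0.221), S phase (0.361) and G2 and mitosis (0.839) lists were not called, and 101 of 142 gene calls that were followed singly were kept. Counts of higher and lower genes were 113 and 708 without NTC replicate 1, 135 and 769 without NTC replicate 2, 163 and 727 without knock-down replicate 1, and 111 and 537 without knock-down replicate 2. They rose to 1034 and 1792 without mESC replicate 1 and to 1030 and 1793 without mESC replicate 2. The spread between replicates over counting noise (chi-square per degree of freedom) was 54.4 in mESC and 40.3 in untreated Sca1 cells. It was 1.54 with the NTC construct and 2.09 in the knock-down, so leaving out a library also changed the shared spread. A lost call thus need not mean that the gene depended on that library. All 1997 calls kept their sign within code 12 and within code 34, though these libraries also made the calls. The share of calls that were higher was 29.7%, and 18.4% when libraries were scaled by their totals only, with 260 higher and 1153 lower.

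The knock-down moved many genes against the direction of differentiation. The comparisons share no library. Across 13966 genes the log2 fold changes had a Pearson r of -0.52 and a Spearman rho of -0.33 (covariance -0.44), genes not being independent replicates. Within pairs of library codes r ranged from -0.51 to -0.42. Of the genes that rose with differentiation, 902 fell in the knock-down, among them Acta2, Col3a1, Dlk1 and Tnc, against 263 for independent lists. Of those that fell, 193 rose, among them Slc13a5, against 99.8. In the same direction, 85 rose and 108 fell in both, against 111 and 236. Opposite signs were thus found in 1095 of 1288 genes called in both (85.0%; two-sided Fisher's exact test over genes, p = 1.93e-82). The 902 genes became 539 without NTC replicate 1, 560 without NTC replicate 2, 543 without knock-down replicate 1 and 414 without knock-down replicate 2. The 193 became 27, 39, 42 and 27 in the same order, and 311 without mESC replicate 1. The counts in the same direction became 24, 23, 25 and 24 for rises and 36, 44, 39 and 29 for falls, and 198 and 192 without mESC replicate 1. Log-CPM profiles of knock-down libraries correlated across genes with NTC libraries at 0.949 to 0.953 and with mESC libraries at 0.924 to 0.940. NTC and mESC libraries correlated at 0.881 to 0.897. On the first principal component (59.5% of variance) the knock-down lay between mESC and the other Sca1 groups, and the second (15.8%) set it apart from all of them.

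**Figure D3:**
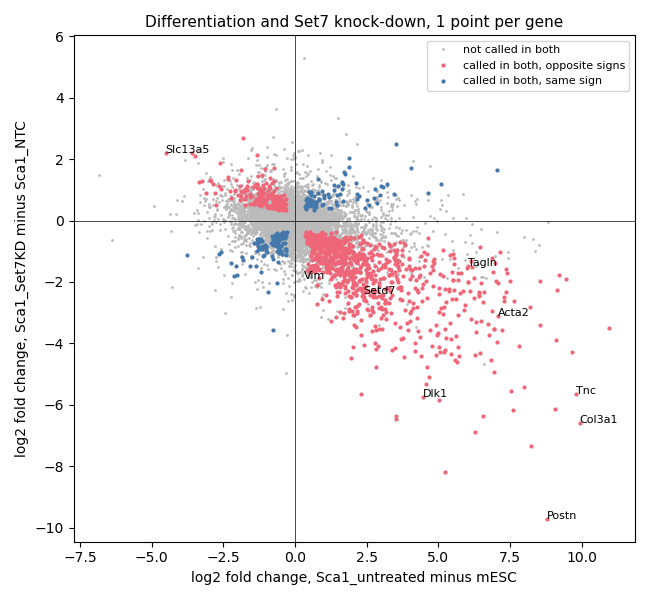
Fitted log2 fold change of each of 13966 genes in untreated Sca1 cells against mESC (horizontal) and in the knock-down against NTC (vertical), with genes called in both comparisons coloured by whether the signs differ. Of 1288 genes called in both, 1095 had opposite signs, and Postn, which had no count in the knock-down, is drawn at its fitted value.

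Genes of chromosome 15 shifted together in the knock-down. The 425 tested genes of this chromosome with a mean of at least 10 CPM had a median change of 0.41 on the log2 scale, against values from -0.16 to 0.05 on the other autosomes. The lowest was that of chromosome 6, where 25.8% of 473 genes were positive. The median was 0.41 in each knock-down library and from -0.09 to 0.11 in the 6 others. Both knock-down libraries and no NTC library carried the shift, so differences between these groups cannot be assigned to Setd7 alone. The shift ran along the whole chromosome, with medians from 0.32 to 0.53 in 8 consecutive bins. Chromosome 15 held 3.89% of tested genes but 177 of the 593 higher calls (29.8%), Tst, Klf10 and Dscc1 among them. The Y-linked genes Ddx3y, Eif2s3y, Uty and Zfy1 were 4.01-fold, 5.65-fold, 6.07-fold and 7.25-fold lower in the knock-down than with the NTC construct, and the sex-linked list was called (camera adjusted p = 0.000139, and 0.204 with an estimated correlation). The call of Zfy1 was lost without NTC replicate 2 (edgeR adjusted p = 0.0867) or knock-down replicate 1 (0.0818), and Kdm5d did not pass (0.270). Xist, the X-inactivation transcript, stood at 17.7 ± 4.19 CPM in the knock-down and 20.8 ± 6.53 CPM with the NTC construct (edgeR adjusted p = 0.682).

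**Figure D4:**
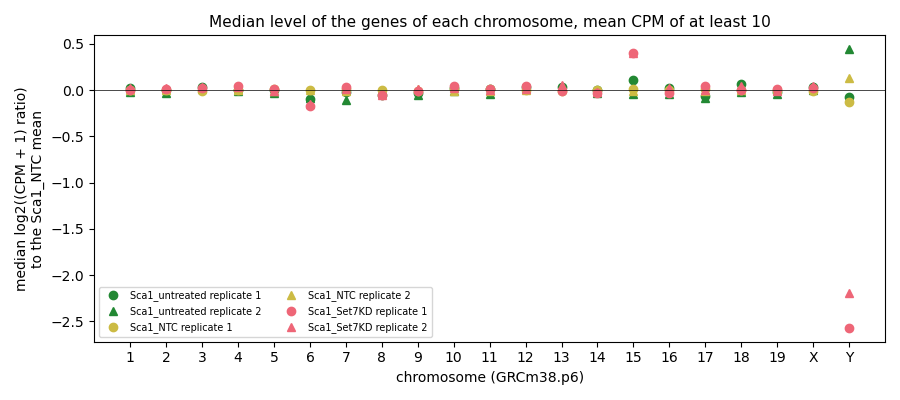
Median over genes of each chromosome of the log2 ratio of CPM + 1 to the NTC mean, 1 symbol per library of the 3 Sca1 groups. The knock-down libraries lie apart from the others at chromosomes 15 and Y.

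The NTC construct was compared with untreated Sca1 cells as the background of transduction and selection. The comparison also holds any other difference between these libraries, which were of codes 12 and 34 with the construct and 34 and 56 without it. Matrix genes were higher with the construct. Col3a1 rose by 1.39 ± 0.11 (250 ± 16.7 to 656 ± 2.10 CPM, n = 2 per group; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 2.83e-06), and Col1a1 by 1.38 ± 0.16. Dlk1 rose by 2.03 ± 0.14 and the endocytic receptor gene Cubn by 1.67 ± 0.14. Setd7 (-0.17 ± 0.17, edgeR adjusted p = 0.628), Acta2 (-0.29 ± 0.21, 0.497), Tagln (-0.44 ± 0.17, 0.152), Cnn1 (0.115), Ly6a (0.423), Pou5f1 (0.361), Nanog (0.773) and Sox2 (0.842) did not pass.

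In this comparison 542 genes were higher and 154 lower, 105 and 21 of them by more than 2-fold. The other largest rises were those of Emilin1, Adamts1, Aebp1, Hoxd4, Dchs1 and Col5a1 (1.31 ± 0.15). The largest falls included those of Dynlt1b (-2.38 ± 0.38), Bex4, Dtx4, Pmaip1, the primitive streak factor Eomes, the actin-sequestering gene Tmsb4x (-1.04 ± 0.12), Dtx1 and Pcdh9. Of 11 lists called, the matrix list alone kept its call with an estimated correlation (22 of 33 rose and none fell, 24 and 1 over the list alone; 0.0282). Among the other 4 that went up, the endoderm genes Amn, Cubn, Col4a1, Lama1 and Lamb1 rose (0.482), 6 of 14 Ly6 and surface genes rose, such as Mcam and Pdgfra (0.249), and the endothelial genes Pecam1, Flt1 and Esam rose (0.249). Hoxa3, Hoxa7, Hoxd3 and Hoxd4 rose among 31 Hox genes (0.249).

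Among lists that went down with the construct, Fgf5 fell in the primed epiblast list (0.623), Gap43 in the neural list (0.249) and Rrm1 in the S phase list (0.638), and no gene of the G2 and mitosis list passed (median -0.20; 0.482). Of the p53 targets Pmaip1, Zmat3, Perp and Ddit4 fell and Tnfrsf10b rose (0.249). The replication-dependent histones had a median of -3.06 with no gene called (0.482). They were themselves higher in untreated replicate 2, of code 56, than in untreated replicate 1 by a median of 2.69. Of 19 such genes 9 were tested, most of which passed the count filter only through the code 56 libraries, so both medians reflect that selection. The other 21 lists were not called (camera adjusted p of 0.0628 to 0.943), and the NF-kB list had a median of 0.11 with a downward test. The sex-linked list had a median of -0.14 and a mean of 0.05 with a downward test.

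Leaving out NTC replicate 1 ended the calls of Amn, Col4a1, Lama1, Lamb1, Esam, Hoxa3, Hoxa7, Hoxd3, Hoxd4, Fgf5, Gap43, Rrm1, Pmaip1, Zmat3, Perp, Ddit4, Tnfrsf10b, Bex4, Dtx4, Eomes, Dtx1, Pcdh9 and Adamts1 (edgeR adjusted p of 0.0508 to 0.344), and that of Dynlt1b was lost without NTC replicate 2 (0.0517). All of these but Amn, Hoxd3, Hoxd4, Adamts1 and Dynlt1b were also lost in other leave-outs, at adjusted p up to 0.369 (Dtx1 without NTC replicate 2). List calls were lost without untreated replicate 1 for p53 targets (0.0531) and S phase (0.1), without untreated replicate 2 for endoderm (0.170), primed epiblast (0.557) and histones (0.172), and without NTC replicate 1 for S phase (0.0758). Higher and lower calls were 54 and 3 without NTC replicate 1, 95 and 2 without NTC replicate 2, 272 and 38 or 266 and 38 without knock-down replicate 1 or 2, and 978 and 523 or 988 and 529 without mESC replicate 1 or 2. They were 337 and 177 without untreated replicate 1 and 297 and 73 without untreated replicate 2. The share of higher calls was 77.9%, and 96.5% with scaling by library totals only, at 491 higher and 18 lower.

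Genes that followed an abundant unnamed non-coding record, NR_046233, separated the libraries of code 56 from the rest. That record took 8.63% and 8.97% of counted reads in mESC replicate 2 and untreated Sca1 replicate 2, 1.17% and 0.815% in the knock-down libraries, and from 0.289% to 0.526% in the 4 others. With it, 30 further genes were over 4-fold higher in the code 56 library than in the code 34 library of the same group, among them Cdk8, Lars2, Rmrp and H1f3. The smooth muscle list holds 1 of these, Filip1l (7693 against 271 CPM in mESC), whose values cannot be told from those of the overlapping Cmss1, and the pluripotency list holds Jarid2. None of the 31 was called in the knock-down comparison. The spread between replicates over counting noise (chi-square per degree of freedom) was 54.4 for mESC and 40.3 for untreated Sca1 cells, against 1.54 with the NTC construct and 2.09 in the knock-down.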

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

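Most alternatives changed how many genes passed, and reported calls changed direction only with untreated Sca1 cells as control. With library totals only, 260 genes were higher in the knock-down and 18 lower with the NTC construct. Genes that rose or fell with differentiation and rose in the knock-down (rise-rise, fall-rise) numbered 48 and 68, and 64 fell in both (fall-fall). DESeq2, run without the count filter on 19467 genes, gave 1558 lower genes with differentiation, and 355 higher and 870 lower in the knock-down. It gave r = -0.34, and 52 rise-rise, 581 rise-fall and 103 fall-rise genes. In edgeR without a count filter, 343 genes were lower with the NTC construct and r was -0.29. The weaker r of DESeq2 can therefore not be assigned to the method. Fitting only the 2 compared groups gave 1981 higher and 2433 lower genes in the knock-down, 348 lower with the NTC construct, and 134 rise-rise, 385 fall-rise and 168 fall-fall genes. A threshold of 1.5-fold left 1311 higher and 730 lower genes with differentiation, 41 and 556 in the knock-down, 14 and 1 with the NTC construct, and 5 rise-rise, 398 rise-fall, 9 fall-rise and 6 fall-fall genes. With the untreated control, whose libraries also serve in the differentiation comparison, 1025 genes were higher in the knock-down, r was -0.61, and 551 were fall-rise and 53 fall-fall. Notch1 then rose by 0.56, and changes past the test against NTC became 0.28 for Pdgfra, 0.0167 for Hspa5, -0.0206 for Cdx1, -0.11 for Ddit4, -0.0662 for Eomes and 0.0658 for Hsp90b1, none past the test. The G2 and mitosis list turned down (adjusted p = 0.839). With this control 13 lists were called, 6 others no longer passing in the same direction (endoderm, Ly6, NF-kB, Wnt, Notch and S phase) and the p53 list passing (0.00223), and 101 of 142 gene calls followed singly were kept. Without the 2 code 56 libraries, an alternative chosen after seeing the data, 1957 and 2505 genes were called in the knock-down and 1300 and 1084 with the NTC construct, with 226 rise-rise, 521 fall-rise and 222 fall-fall genes. Without genes of chromosomes 15 and Y, also chosen later, 429 genes were higher and 1282 lower in the knock-down and 17 lists were called, Zscan4c (0.0558) and the Wnt targets (0.0684) no longer passing and the sex-linked list no longer tested. With an estimated correlation 5, 3 and 1 lists were called in the 3 comparisons, and fry called 7 with the NTC construct. Library similarity with a prior count of 0.5 was 0.918 between knock-down and mESC, 0.942 between knock-down and NTC, and 0.864 between untreated Sca1 and mESC. The labels do not say that the number in the sample descriptions, which goes with the library code, marks a batch. It gives 2 pairs in the differentiation and knock-down comparisons, and 1 in the NTC comparison, where the groups share only code 34. Deviations of same-numbered libraries correlated at 0.39 for mESC with untreated Sca1 and 0.23 for NTC with knock-down. With the number as a block, 1054 genes were higher in the knock-down and 819 higher and 442 lower with the NTC construct, with 180 rise-rise, 362 fall-rise and 193 fall-fall genes. The block kept 597 of the 696 NTC calls and called 8 lists there instead of 11. The primed epiblast, endoderm, neural and Hox lists no longer passed (adjusted p of 0.0603 to 0.137), nor did Dtx4, Eomes, Dtx1, Fgf5 and Perp (0.0974 to 0.172) or, in the knock-down, the Wnt targets (0.0560). Leaving out single libraries gave 2109 to 2918 higher and 1668 to 2777 lower genes with differentiation, 111 to 1034 and 537 to 1793 in the knock-down, and 54 to 988 and 2 to 529 with the NTC construct. Rise-rise genes numbered 23 to 198, rise-fall 414 to 1005, fall-rise 27 to 311 and fall-fall 29 to 192. Where a group kept 1 library, its spread was taken from the others. A call lost there can reflect this change of spread and need not mean dependence on the library left out. The Setd7 change in the knock-down stayed between -2.56 and -2.18, and r between -0.51 and -0.45. Of the 4963, 1997 and 696 calls of the 3 comparisons, RLE factors kept 4947, 1941 and 659, the 1.5-fold threshold 2041, 597 and 15, and single leave-outs at least 3512, 646 and 57. The untreated control kept 1204 of the 1997 and gave 2 the opposite call, Notch1 and Plxnb2.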

Other observations

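All observations here were chosen after the results were seen. Some genes fell in the knock-down below the level of undifferentiated cells as well as of NTC cells. Pcolce, an enhancer of collagen processing, stood at 119 CPM in mESC, 119 CPM with the NTC construct and 10.1 CPM in the knock-down. Vim stood at 515, 479 and 129 CPM, the basement membrane gene Nid1 at 349.7, 275.7 and 97.8 CPM, the adhesion gene Mcam at 159, 93.9 and 27.4 CPM, and the hypoxia factor gene Epas1 at 68.4, 67.8 and 17.7 CPM. In all, 274 genes were lower than in both groups, or 250 when the 21 Pcdhg genes that share reads, unnamed records and repeats of identical counts were left out. The comparisons share the knock-down libraries, so they are not independent. Against untreated Sca1 cells some of the 274 genes, such as Lama1 and Pdgfra, were not called lower in the knock-down.

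In the ATF4 and unfolded protein response list, 6 of 20 tested genes rose in the knock-down, 6 fell and 8 did not pass (camera adjusted p = 0.788). Those that rose included Chac1 (2.05 ± 0.32), Trib3 (1.26 ± 0.22) and Atf4 (0.96 ± 0.17), the last on chromosome 15, and those that fell included the chaperone genes Hspa5 (-0.71 ± 0.12) and Pdia4 (-0.91 ± 0.11). No division of the list was tested, and against untreated Sca1 cells Hspa5 did not fall (0.0167) and Atf4 (0.36) and Pdia4 (-0.15) did not pass. Of 22 tested genes of the Pcdhg protocadherin cluster, which share reads, all 22 rose with differentiation and all 22 fell in the knock-down, and 20 rose with the NTC construct. Chromosome 6 carried 2 higher and 78 lower calls of the knock-down, with a median of -0.16.

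The chromosome 15 and Y pattern had 1 test written before its result, on copy number, and the others after. A copy number change would move chromosome 15 genes by a common amount. Their spread was 0.999 of that of other autosomal genes around a median of 0.41, which is consistent with extra copies of chromosome 15 in a share of the knock-down cells. Library depth did not explain it, as the smaller of the medians within codes 12 and 34 was 0.39, nor did composition acting through the scaling, which would move the other autosomes as well, as the smaller difference from their median was 0.389. DNA was not analysed here, so copy number itself remains unmeasured.

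For the lower calls of the knock-down, the seed test was written before its result and the others after. A mixture of NTC-like with mESC-like cells would leave few genes below both, by chance alone (at most 0.812% of lower calls in 10 simulated mixtures each at 50% and 82.8% mESC-like cells, which reused the same libraries in both comparisons), yet 19.7% of lower calls outside chromosomes 15 and Y lay also below mESC, and 18.6% without chromosome 6, Pcdhg genes, unnamed records and repeats of identical counts (227 of 1217). It would also leave 1 common share of genes near absent in mESC. Yet the 90th over the 10th percentile of the share kept was 12.7 over 73 genes, against 1.61 in simulations. The counts below both groups and the simulations took NTC cells as the only Sca1 profile and the mESC libraries as the only undifferentiated profile. Undifferentiated cells with another profile than these libraries were not simulated, so the counts below both groups do not speak to a mixture with such cells. With untreated Sca1 cells as control, 1204 of the 1997 knock-down calls were kept. Genes below both groups such as Lama1 and Pdgfra were then not called lower. Other runs of neighbouring genes were not looked for, so shifts of further regions could contribute to the genes below both groups. Seed sites of the shRNA were in 12.7% of lower calls with a 3' UTR and in 11.4% of genes not called. Direct off-target silencing through the seed could therefore explain few lower calls (odds ratio at equal UTR length 1.02, 95% interval 0.853 to 1.22). Genes changed downstream of an off-target gene need hold no site, so the test does not cover them. The chromosome 15 and Y difference was in 2 of 2 knock-down libraries, so its effects cannot be separated from those of Setd7 loss, and loss of a mesenchymal cell type was not tested.

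For the genes that follow NR_046233, both tests were chosen after the result was seen. Replication-dependent histone transcripts lack poly(A) tails. They were higher in the code 56 library by a median of 2.69 in untreated Sca1 cells and 2.94 in mESC. Of 19 such genes 9 were tested. Most of these passed the count filter only through the code 56 libraries and met the rule that defined the set. The medians were therefore largely fixed by selection and cannot show whether removal of RNA without tails was less complete. From NTC to knock-down, outside code 56, the 13 other genes of the set with at least 10 CPM had a median change of 1.74 and the record one of 1.58, none past the test. Reads of the record counted on genes that share its sequence could therefore contribute. The histones had a median of 0.95 there (7 of 9 positive) with none past the test (camera adjusted p = 0.430), so these values do not separate the explanations.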
